A study of Drosophila melanogaster with 2 samples.

How the data were processed

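The series holds ChIP-seq peak lists from 2 biological replicates of whole Drosophila embryos, 0 to 24 hours old, expressing CG1024-eGFP. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP. Per the deposited inventories, each replicate's lists derive from that replicate's alignments and a control, and the series-level lists from both replicates. Peaks were thus called per replicate and also for both together. The aligner, the peak caller and their versions are not given in the sources used here. The build is dm6, per the labels.

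Each list gives a signal per peak, the authors' own peak caller value with no stated scale, and a score, which the authors scaled from the irreproducible discovery rate (IDR) to at most 1000. The ranked lists add the −log10 of the local and global IDR, as the authors deposited them, and 8 further columns without a header that were not used. The p column of the deposited lists is -1 throughout. Every row of each thresholded list was found in a ranked list at a global IDR of 0.01 or below. Of the ranked rows at that level, 101 of 3502 behind the conservative set, 141 of 4133 behind the other series-level set, 87 of 2686 in replicate 1 and 114 of 2405 in replicate 2 were left out of the thresholded lists by a step not given in the sources used here. No list holds read counts, so depth is unknown, and the intervals given for shares cover counting of peaks, genes or windows only.

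Peak coordinates were converted to 1-based positions. All peak ends fell within the chromosome lengths of the reference FASTA for the same build. Genes and TSSs came from Ensembl release 115. Apart from the counts and quantiles of each list and the observed replicate overlap, analyses used 7 chromosomes (2L, 2R, 3L, 3R, 4, X and Y). This leaves out 4 of the 3401 conservative peaks. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and overlaps were counted with bedtools 2.31.1.

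The choices that follow were made before the data were examined, except where stated. A promoter summit lies within 500 bp of any annotated TSS; other classes follow in the order 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Shares were compared with 1000 random placements on sequenced bases of the same chromosome. Median signals were compared with 100000 permutations. For replicate correlations, a conservative peak took the highest signal among a replicate's overlapping ranked peaks. The 17 gene lists and 22 motifs were fixed in advance, and 3 list symbols matched no gene. Gene lists were compared with all other protein-coding genes by Fisher's exact test. Odds ratios were computed with 0.5 added to each cell. Windows of 100 bp each side of a summit were compared with 1 background window per peak, 1 to 5 kb away and clear of every peak of the 4 thresholded lists. Of these windows, 2991 matched in promoter class and in GC content within a 5 percentage point bin, and 190 in class only. The other 215 did not match in class, whatever their GC content. The 8-base sequences were found in odd-ranked peaks and re-tested in even-ranked peaks. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05.

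Named genes are CG1024; the genes with a TSS within 500 bp, or otherwise the nearest, of the 15 strongest conservative peaks overlapping a thresholded peak of each replicate; up to 3 members per list with the strongest promoter summit, or all for lists of 10 or fewer; and the nearest gene of the 5 strongest peaks over 1000 bp from any TSS.

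The functions were tested on simulated data. With summits placed at random, 0 of 17 gene lists passed, and background windows set against other background windows gave 0 motifs of 22 and 0 sequences of 8 bases over 3397 windows. Of 10 sequences planted in windows, 9 were recovered in the even-ranked peaks. With summits planted at ribosomal protein genes, that list was the 1 called of 17.

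Alternatives were the other series-level set, each replicate alone, the peaks of above-median signal, TSS windows of 200 and 1000 bp, the 5 large chromosomes alone, motif windows of 50 bp, a background without GC matching and 2 other definitions of overlap. Added after seeing the data were global IDR levels of 0.05 and 0.001, further background draws, the removal of chromosome 4 and of centromere-proximal windows, and the removal of windows that share 25 bases.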

Results

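Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to ask where a fusion of the CG1024 gene product to enhanced green fluorescent protein (eGFP) sits on the genome of whole Drosophila melanogaster embryos. The embryos were 0 to 24 hours old, and chromatin was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates and no second condition, so the comparisons below are between replicates, between parts of the genome and between groups of genes. The data are peak lists on genome build dm6, 1 pair per replicate and 2 pairs for both replicates together. Peak signal is the authors' own value for each peak. Its levels are compared only within a list, while the replicates' values are also correlated and printed beside pooled ones. The lists hold no read counts, so the depth behind each peak is unknown.

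Most thresholded peaks of each replicate overlapped a peak of the other. Replicate 1 had 2599 thresholded peaks and replicate 2 had 2291, a ratio of 1.13. Of the replicate 2 peaks, 1656 (72.3%, 95% Wilson interval 70.4 to 74.1) overlapped a replicate 1 peak by at least 1 bp, and of the replicate 1 peaks 1662 (63.9%, 62.1 to 65.8) overlapped a replicate 2 peak. Shuffling the peaks within their chromosomes left a mean overlap of 0.939% and 0.838%, and none of 1000 shuffles reached the observed value (one-sided permutation test, p = 0.0010, the smallest it can give). The conservative set of the series, used for all that follows, held 3401 peaks with a median width of 280 bp. Its median signal was 90.9, with quartiles of 66.9 and 142 and a maximum of 1675. The other series-level set held 3992 peaks, 1.17 times as many. Across the 3347 conservative peaks that had a ranked peak in each replicate, the replicates' signals had a Spearman rho of 0.731 and, on the log10 scale, a Pearson r of 0.871. These correlations are across peaks, which are not independent replicates, and over a set that was itself selected by IDR for like rank. Over the other series-level set rho was 0.651. In all, 1651 conservative peaks (48.6%) overlapped a thresholded peak of both replicates, and 816 overlapped a thresholded peak of neither.

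More of the fusion protein's summits lay at promoters than in any other class. Of 3397 summits on the 7 chromosomes, 1659 (48.8%, 95% Wilson interval 47.2 to 50.5) lay within 500 bp of an annotated transcription start site (TSS), 3.60 times the 13.6% of shuffled positions. Coding exons held 1.44% of summits against 13.8% of shuffled positions, and 3' UTRs held 0.795% against 4.43%. Introns held 32.0% against 39.3% and intergenic sequence 15.5% against 27.3%. These 5 classes passed the test (two-sided permutation test with 1000 shuffles, adjusted p = 0.0028 each). The 5' UTR beyond the promoter class (0.50% against 0.776%, adjusted permutation p = 0.0862) and non-coding exons (0.913% against 0.811%, adjusted permutation p = 0.575) did not. With replicate 2 alone the lower 5' UTR share passed (0.398%, adjusted permutation p = 0.0466), and coding exons held 0.577% and 0.752% of summits with replicate 1 and replicate 2 alone. Promoter summits also had the higher signal, with a median of 99.5 against 84.6 for the 1738 other summits, a difference of 14.9 (two-sided permutation test with 100000 resamples, p = 1.0e-05, the smallest it can give). The difference was 5.36 with replicate 1 alone (permutation p = 8.0e-05), in that list's own signal, and 30.5 among the peaks of above-median signal.

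The 15 strongest peaks found in both replicates had signals from 1190 to 1675, and 14 of them had a TSS within 500 bp. The highest was at MED21 (FBgn0040020), which encodes a subunit of the Mediator complex. That peak spans 25115830 to 25116149 on 3L, with its summit at 25115980, 34 bp upstream of the TSS, and a signal of 1675 (765 in replicate 1 and 909 in replicate 2). CG40045 (FBgn0058045, 3L, summit 24028454) followed with 1554, and Dbp80 (FBgn0024804, 3L, summit 27279269), a DEAD-box RNA helicase gene, with 1370. Gyf (FBgn0039936) had a summit at 867109 on chromosome 4, 84 bp upstream of its TSS, with a signal of 1367. Mitochondrial respiratory chain genes among the 15 were ND-AGGG (FBgn0058002, 3L, summit 24976182, signal 1322), a complex I subunit gene, and UQCR-11 (FBgn0260008, 3L, summit 25120675, signal 1195), a complex III subunit gene. RNASEK (2R, summit 4188220) had 1315, CG40228 (3L, summit 27083969) had 1277 and l(3)80Fg (3L, summit 26014224) had 1275. On chromosome 4 the summits at anne (132146), at the ribosomal protein gene RpS3A (67303) and at the plexin receptor gene PlexB (43823) had signals of 1264, 1223 and 1221. Ugalt, a UDP-galactose transporter gene, was the only one of the 15 on the X chromosome (summit 2703882, signal 1201), and CG14464 (2R, summit 4829199) had 1190. The 14 promoter summits lay 30 to 112 bp from the nearest TSS of the named gene, each on its upstream side. The remaining peak (2R, 4012656 to 4012929, signal 1219) lay in intergenic sequence, 1322 bp upstream of Haspin, which encodes a histone H3 kinase.

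Away from promoters, 1387 summits (40.8%) lay over 1000 bp from any TSS. After the peak near Haspin, the strongest of these was an intergenic peak at 3789666 to 3789945 on 3R with a signal of 936, 39448 bp from the TSS of CG41128, the nearest. Intronic peaks at CG11050 (2L, summit 6612726, 1039 bp downstream of a TSS) and at d4 (2R, summit 5260684, 1680 bp downstream) had signals of 911 and 845. An intergenic peak at 13035235 to 13035443 on 2R had a signal of 754, 11909 bp from the TSS of CG13323. The genes named for these distal peaks are those with the nearest TSS, and most of them also had a promoter summit of their own.

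Chromosome 4, the small autosome that carries 80 protein-coding genes in the annotation, stood apart from the other chromosomes. It held 45.8 peaks per Mb (95% Poisson interval 35.1 to 58.9), against 26.8 on 2L, 26.1 on 2R, 27.0 on 3L, 21.9 on 3R and 25 on X. A summit lay within 500 bp of a TSS at 39 of its 80 genes (48.8%, 38.1 to 59.5), against 13.9% of genes elsewhere (odds ratio 5.87, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 7 chromosomes, adjusted p = 1.0e-12). The odds ratio was 10.2 with replicate 1 alone and 11.2 among the peaks of above-median signal. The median signal of its 61 peaks was 304, and on 2L, 2R, 3L, 3R and X the medians ran from 87.0 to 94.2. Genes on 2L, 2R, 3L and 3R had a summit at shares of 13.7% to 14.7%, with adjusted exact p from 0.578 to 0.928. The X had 12.9% (odds ratio 0.882, adjusted exact p = 0.155). With the TSS window at 200 bp, the other series-level set, the peaks of above-median signal or replicate 2 alone, the lower share on X passed the test (odds ratios 0.775, 0.845, 0.790 and 0.738). The Y chromosome had 2 peaks and a summit at 0 of its 23 genes (adjusted exact p = 0.155), which allows a share of up to 14.3%.

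**Figure D1:**
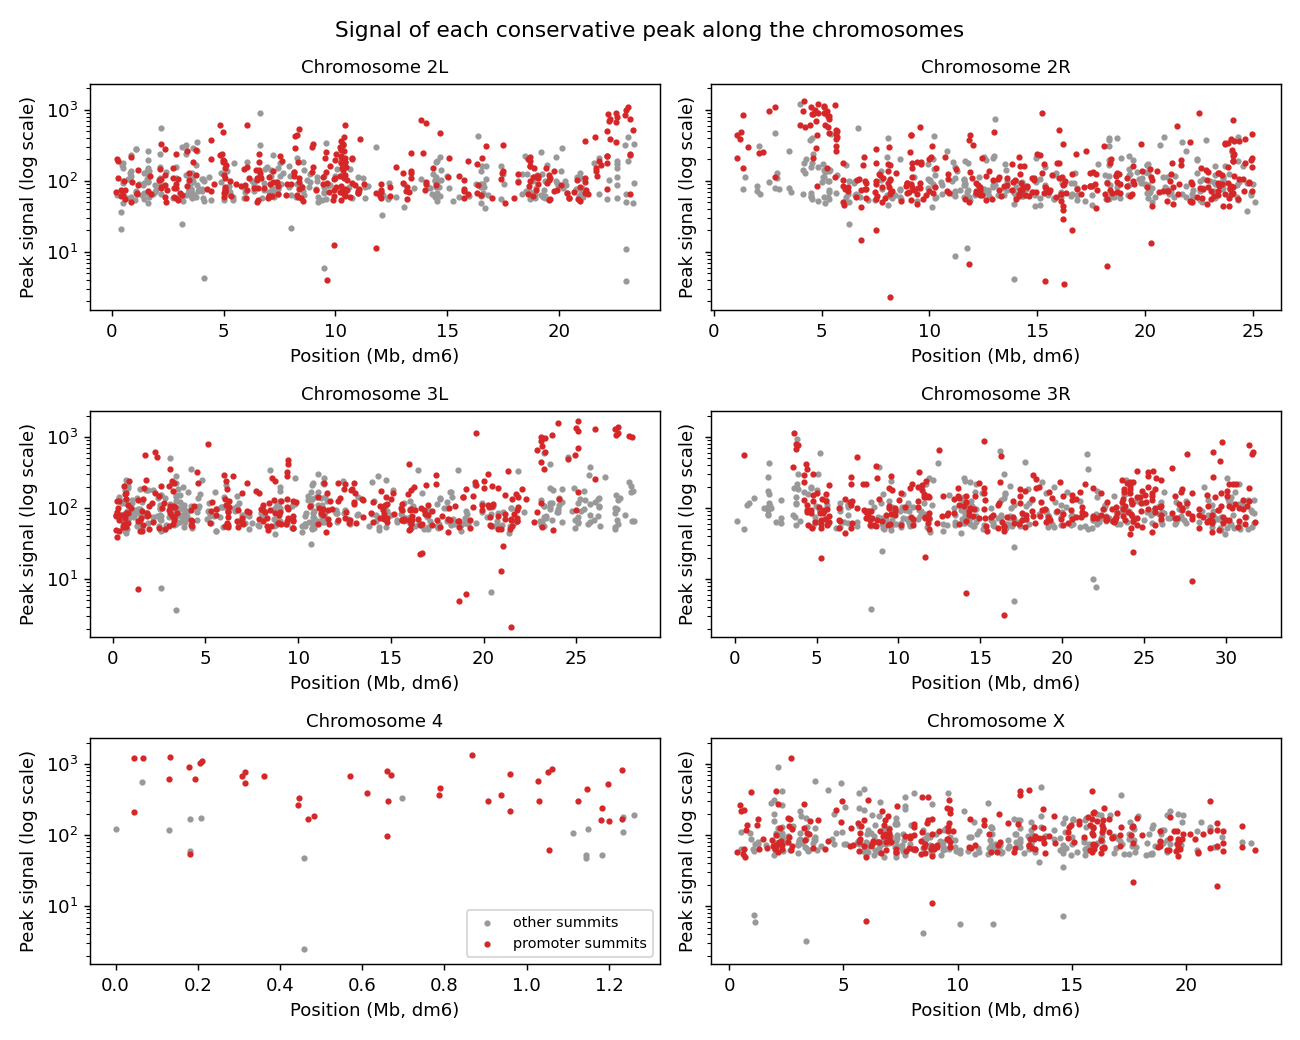
Signal of each conservative peak (vertical axis, log scale, the authors' units) against its summit position in Mb (horizontal axis) on 6 chromosomes, with promoter summits in red and all other summits in grey. The highest points lie near the right end of 2L and 3L, toward the left end of 2R and 3R, and along chromosome 4, where the median signal was 304.

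Cytoplasmic ribosomal protein genes carried summits far more often than other genes. Over the genome, 1975 of 13968 protein-coding genes (14.1%, 95% Wilson interval 13.6 to 14.7) had a summit within 500 bp of a TSS. Of the 88 ribosomal protein genes, 57 did (64.8%, 54.4 to 73.9), against 13.8% of all other genes (odds ratio 11.4, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 17 lists, adjusted p = 1.93e-26). The strongest were RpS3A on chromosome 4 (signal 1223), RpL15 on 3L (summit 27267181, signal 1146) and RpL38 on 2R (summit 4516555, signal 1103). Genes of insulator and other architectural proteins had a summit at 6 of 15 (40.0%, odds ratio 4.16, adjusted exact p = 0.0430), led by Clamp (2L, summit 22169259, signal 874), Chro (3L, summit 22878902, signal 663) and Trl, the GAGA factor gene (3L, summit 14757227, signal 143). Polycomb and trithorax group genes, which keep developmental genes silent or active, had a summit at 7 of 19 (36.8%, odds ratio 3.65, adjusted exact p = 0.0430). The strongest were brm, the ATPase gene of a chromatin remodelling complex (3L, summit 15982999, signal 416), ph-p (X, summit 2137883, signal 271) and pho on chromosome 4 (summit 1182017, signal 244). Both of these calls were lost when chromosomes 4 and Y were left out with odds ratios of 4.22 for insulator proteins (adjusted exact p = 0.0506) and 3.21 for the Polycomb and trithorax group (0.104), and when chromosome 4 and windows next to the centromeres, bounded by eye after seeing the data, were (odds ratios 3.41 and 3.39, adjusted exact p = 0.116 and 0.105). The insulator list also lost it with a 1000 bp TSS window (odds ratio 3.39, adjusted exact p = 0.0964), and the Polycomb and trithorax list among the peaks of above-median signal (4.32, adjusted exact p = 0.0521). Higher odds ratios past the threshold were found for insulator proteins with replicate 1 alone (6.89) and among the peaks of above-median signal (7.81), and for the Polycomb and trithorax group in the other series-level set (5.75).

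Genes of chemoreceptors and of cuticle proteins had a summit less often than other genes. None of the 179 chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, had one (upper Wilson bound 2.10%, adjusted exact p = 1.81e-11). None of the 70 Cpr cuticle protein genes had one either (upper bound 5.20%, adjusted exact p = 0.000226). The other 12 lists did not pass the test. Mitochondrial ribosomal protein genes had a summit at 16 of 73 (21.9%, adjusted exact p = 0.150), led by mRpL41 (2R, signal 903), mRpS10 (3R, signal 877) and mRpS23 (2L, signal 728). Oxidative phosphorylation genes had one at 16 of 92 (17.4%, adjusted exact p = 0.567), led by ND-AGGG, UQCR-11 and ND-49 on chromosome 4 (signal 692). Proteasome genes had one at 4 of 48 (8.33%, adjusted exact p = 0.516), with the strongest summits at Prosbeta1 (2R, signal 181), Prosalpha6 and Rpn3 (both 2L). Heat shock genes had one at 6 of 20 (30%, adjusted exact p = 0.149), including Hsp27 (3L, signal 283), Hsp83 (3L, signal 243) and Hsc70-4 (3R, signal 162). Cell cycle and replication genes had one at 8 of 31 (25.8%, adjusted exact p = 0.150), including CycD (signal 128), Dp (114) and RnrS (110).

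For Hox, segmentation, dorsoventral, neural, muscle and ecdysone genes no difference from other genes was detectable. No Hox gene of 8 (adjusted exact p = 0.790) and no neural fate gene of 17 (adjusted exact p = 0.293) had a promoter summit. Segmentation genes had one at 2 of 25 (8.0%, adjusted exact p = 0.790), namely nkd (3L, signal 184) and bcd (3R, signal 133), the maternal determinant of the anterior. Dorsoventral genes had one at 3 of 17 (adjusted exact p = 0.790), at rho, ush and brk, with signals of 66.9, 63.3 and 57.6. Neuron function genes had one at 3 of 17 (adjusted exact p = 0.790), at elav (X, signal 220), Snap25 (3L, signal 133) and Nrx-1 (3R, signal 96.8). Muscle genes had one at 3 of 19 (adjusted exact p = 0.790), at the heart regulator tin (3R, signal 218), sls (3L, signal 119) and Mef2 (2R, signal 70.7). Ecdysone genes had one at 2 of 18 (adjusted exact p = 1), at usp (X, signal 99.8) and Eip75B (3L, signal 46.6). The peaks at brk, Mef2 and Eip75B were in the thresholded list of neither replicate, and those at rho and ush only in that of replicate 1. With so few members, shares in these lists are known only within wide intervals, from 0% to 32.4% for the Hox genes.

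**Figure D2:**
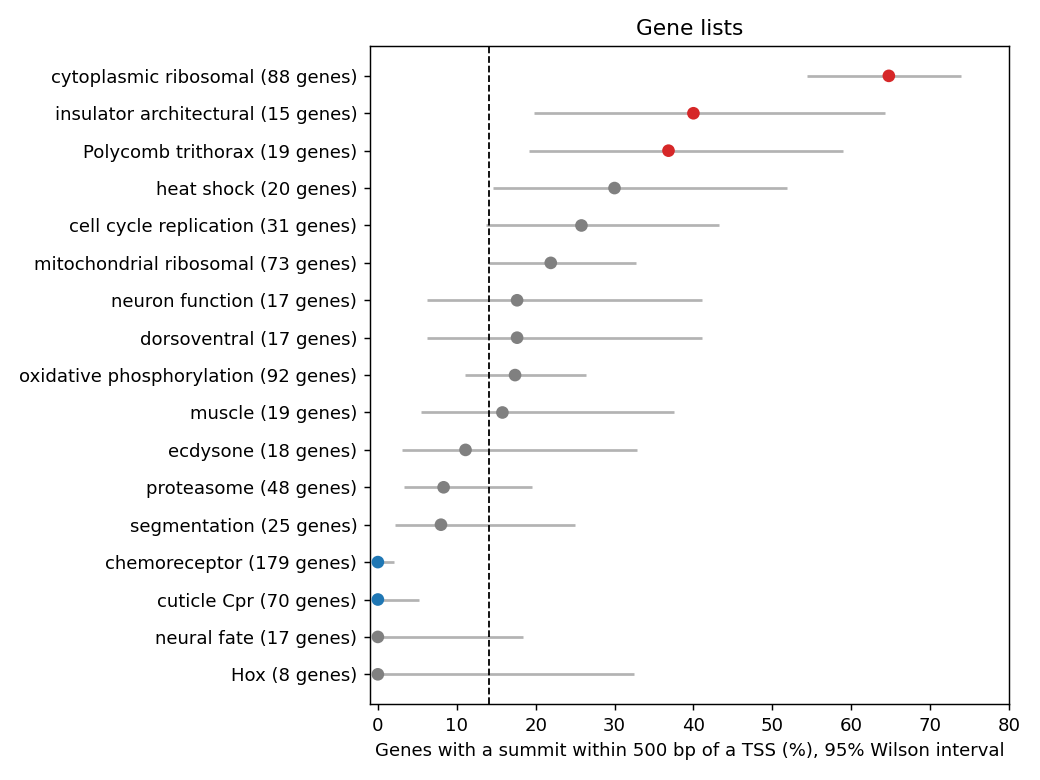
Share of the genes of each list with a summit within 500 bp of a TSS (horizontal axis, percent, points) with 95% Wilson intervals (lines). The dashed line is the share of all protein-coding genes, 14.1%; red lists had a higher and blue lists a lower share past the adjusted threshold, and the cytoplasmic ribosomal list lies at 64.8%.

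The CG1024 gene itself (FBgn0027514, 3R, 6377349 to 6380328) had no conservative summit within 500 bp of its TSS. The nearest lay 11380 bp away at 6368827. The ranked list placed 5 peaks within 500 bp of the gene body, the strongest with a signal of 21.5, all below the threshold. Genes of transfer RNAs, transcribed by RNA polymerase III, had a summit within 500 bp at 9 of 290 (3.10%, 95% Wilson interval 1.64 to 5.79), against a mean of 2.68% after shuffling (two-sided permutation test, p = 0.783). A difference was not detectable for this class.

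Among 22 known motifs, those of CTCF, Dref and BEAF-32, Ohler 7 and M1BP were the most over-represented around summits of those that passed the test. Background windows were matched on promoter class where possible but not on distance from the TSS, so an excess was not separated from position at the TSS. The same holds for the 8-base sequences below. A CTCF motif lay within 100 bp of 81 of 3396 summits (2.39%) and in 7 background windows (0.206%), an odds ratio of 11.1 (two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 motifs, adjusted p = 6.58e-16). The DNA replication-related element TATCGATA, bound by Dref and BEAF-32, was in 4.27% against 1.27% (odds ratio 3.45, adjusted exact p = 1.33e-13). The core promoter element Ohler 7 was in 5.86% against 2.00% (odds ratio 3.03, adjusted exact p = 1.31e-15), and the M1BP motif in 1.30% against 0.530% (odds ratio 2.42, adjusted exact p = 0.0045). The E-box CAGCTG was in 9.10% against 7.21% (odds ratio 1.29, adjusted exact p = 0.0143). Motifs of Snail (5.42% against 7.16%, adjusted exact p = 0.0116), Bicoid (6.10% against 8.19%, adjusted exact p = 0.0042) and the heat shock factor HSF (2 against 17 windows, adjusted exact p = 0.0039) were rarer at summits. The other 14 motifs did not pass, among them GAGA (3.39% against 2.86%, adjusted exact p = 0.432), Zelda (0.736% against 0.883%, adjusted exact p = 0.828), the initiator (17.2% against 17.6%, adjusted exact p = 0.828), the TATA box (5.54% against 5.45%, adjusted exact p = 0.959) and Su(Hw) (0.972% against 0.589%, adjusted exact p = 0.214). In 10 further random draws of the background, made after seeing the data, the CTCF, TATCGATA, Ohler 7 and M1BP calls held in all 10. Those of the E-box, Bicoid, Snail and HSF held in 7, 5, 4 and 3, and Ohler 6 (odds ratio 1.98, adjusted exact p = 0.0858 in the draw used for all other values) passed in 8. The CTCF odds ratio was 7.24 with another background draw and without GC matching, and 6.87 in the other series-level set. Without GC matching that of TATCGATA was 5.29 and that of the E-box 0.972. The M1BP call was lost among the peaks of above-median signal, with an odds ratio of 2.33 (adjusted exact p = 0.0712), and the odds ratio was 5.02 with windows of 50 bp. The E-box and Snail calls were also lost in the other series-level set (adjusted exact p = 0.0516 and 0.110), among the peaks of above-median signal (0.283 and 0.469), on 2L, 2R, 3L, 3R and X alone (0.178 and 0.138) and with windows of 50 bp (0.291 and 0.108). In these settings the E-box odds ratio was 1.17 to 1.23. The HSF call was lost on 2L, 2R, 3L, 3R and X alone (adjusted exact p = 0.240) and with windows of 50 bp (0.424), as was that of Bicoid with windows of 50 bp (0.385). GAGA passed in the other series-level set (odds ratio 1.47, adjusted exact p = 0.0080). Ohler 6 passed without GC matching (3.23, adjusted exact p = 0.0032) and on 2L, 2R, 3L, 3R and X alone (2.58, 0.0295), and without GC matching so did the Su(Hw) (2.32, 0.0189) and homeobox (1.37, 3.9e-05) motifs. With replicate 1 alone the E-box, Snail and HSF calls were lost (adjusted exact p = 0.141, 0.841 and 0.274) and GAGA and Ohler 6 passed (0.0176 and 0.0328); with replicate 2 alone the Snail and HSF calls were lost (0.950 and 0.359) and the Su(Hw) motif passed (0.0423).

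**Figure D3:**
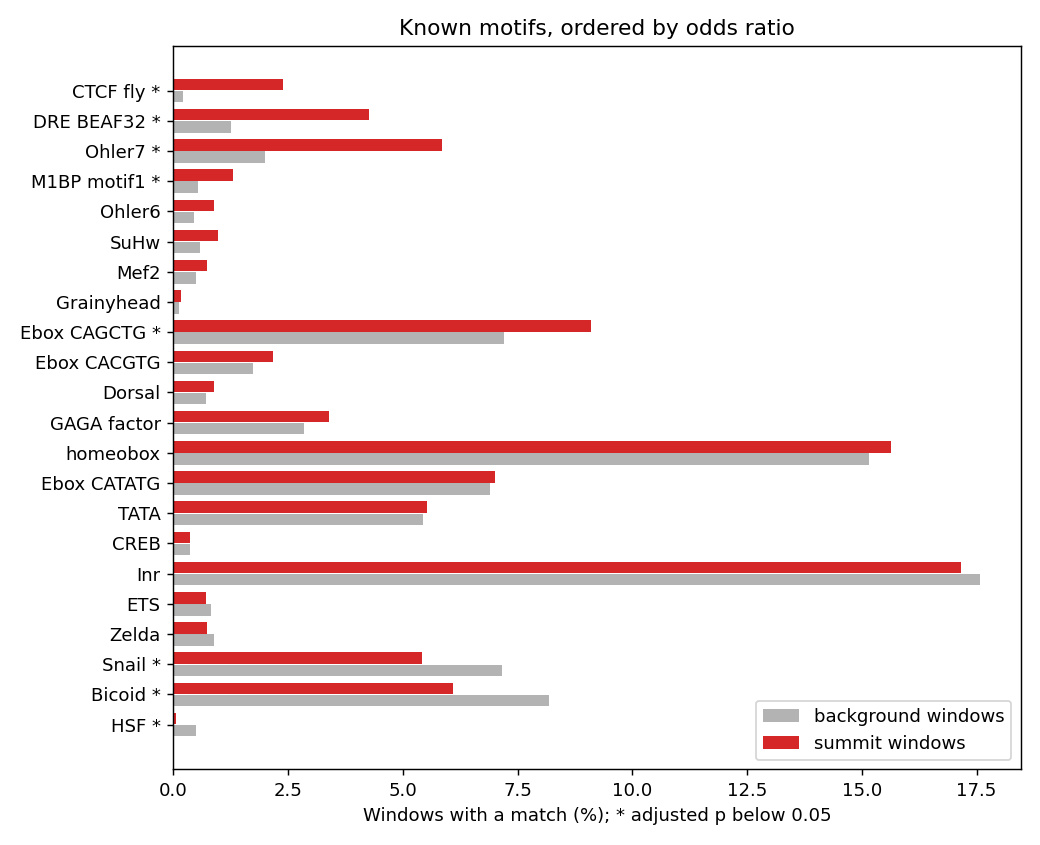
Percent of windows reaching 100 bp each side of the summit (red) and of matched background windows (grey) with a match to each known motif (horizontal axis), ordered by odds ratio. Stars mark adjusted p below 0.05; the CTCF motif at the top was in 2.39% of summit windows and 0.206% of background windows.

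A search over all 8-base sequences returned many that held CACTG or CAGTG. Of 32839 sequences seen, 63 passed in the odd-ranked peaks, and 56 of these passed again in the even-ranked peaks, which were not used to find them. Of the 56, 30 held CACTG or its reverse complement CAGTG, counted without regard to strand. The sequence with the lowest p in the odd-ranked peaks, CACAGTGG (CCACTGTG on the other strand), called leading here, was in 71 of 1698 even-ranked summit windows and 12 background windows (odds ratio 5.93, one-sided Fisher's exact test, adjusted p = 1.50e-10). CACTGTGC was in 84 against 14 windows (odds ratio 6.08, adjusted exact p = 1.85e-12), CACTGAGA in 70 against 12 (odds ratio 5.84, adjusted exact p = 1.96e-10) and TCAGTGCA, which had the lowest p in the even-ranked peaks, in 74 against 6 (odds ratio 11.9, adjusted exact p = 8.54e-15). TATCGATA came back as well, in 86 against 23 (odds ratio 3.82, adjusted exact p = 2.37e-09). At least 1 of the 56 was in 66.7% of the even-ranked summit windows and 41.0% of their background windows. As the 56 were kept for passing in these same windows, the difference is not an independent test. They include A/T-rich sequences common in both, such as AAAAAAAT (207 against 160 windows). The shares are thus not those of sequences with CACTG or CAGTG alone. With replicate 2 alone 27 sequences passed both steps, with replicate 1 alone 31 and among the peaks of above-median signal 13. With windows of 50 bp in place of 100 bp 1 passed, and without GC matching of the background 162 did.

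The leading sequence lay less often at the summit than some distance from it. In the even-ranked peaks CACAGTGG lay within 25 bp of 10 of 1698 summits (0.589%) and 75 to 100 bp away at 26 (1.53%), an odds ratio of 0.392 (two-sided Fisher's exact test, p = 0.0109). The same summits give both counts, a pairing that this test ignores here and in the alternatives that follow. The odds ratio stayed below 1 but missed the threshold in the other series-level set (0.556, exact p = 0.0708), with replicate 2 alone (0.459, exact p = 0.0598) and with replicate 1 alone (0.673, exact p = 0.359). Among the peaks of above-median signal it was 0.0753 (exact p = 3.65e-05).

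**Figure D4:**
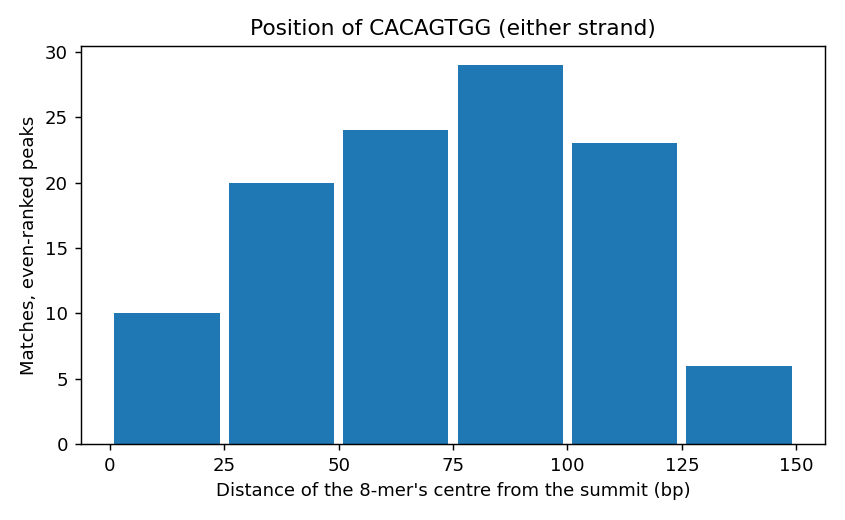
Number of matches to CACAGTGG on either strand in the even-ranked peaks (vertical axis) by the distance of the match's centre from the summit in steps of 25 bp (horizontal axis). The first bar, within 25 bp, holds 10 matches and the highest bar, 75 to 100 bp away, holds 29.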

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

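Peaks on unplaced sequences numbered above the 3 that a count of 0 allows in 3 of the 4 thresholded lists. They entered the peak counts, the quantiles of each list and the observed replicate overlap, but not the shuffles or the other comparisons. The conservative set had 4 such peaks, the other series-level set 12 and replicate 2 had 31, against 1 in replicate 1. Control samples were not analysed here, and no explanation was tested.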

How the results depend on the processing

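The promoter share (38.0% to 59.2%), the higher signal at promoters, the replicate overlap (67.0% to 80.8%) and the ribosomal, chemoreceptor and Cpr calls kept their direction and their side of the threshold under every alternative run for each, as did the share on chromosome 4. The count of re-tested sequences of 8 bases moved from 56 to 162 without GC matching, 1 with 50 bp windows, 13 among the peaks of above-median signal, and 27 to 31 with either replicate left out. Gene lists past the threshold fell from 5 to 3 on the 5 large chromosomes, and to 3 without chromosome 4 and the centromere-proximal windows, an alternative chosen after seeing the data. Known motifs fell from 8 to 4 with 50 bp windows and to 5 among the peaks of above-median signal. Of 108 alternative values for single motifs, 20 lost a call, 8 gained one and 4 changed direction, and of 40 for single gene lists 6 lost a call. Chromosomes past the threshold numbered 2 (chromosome 4 and X) in place of 1 with a 200 bp TSS window, in the other series-level set and among the peaks of above-median signal, and 1 to 2 with either replicate left out. The position odds ratio of the leading sequence was 0.556 in the other series-level set and 0.459 to 0.673 with either replicate left out. The replicate correlation was 0.651 over the other series-level set. The conservative ranked list held 5360 peaks at a global IDR of 0.05 and 1901 at 0.001, both chosen after seeing the data; the planned level of 0.01 (3502) is the authors' own. The tRNA share fell below its shuffled mean with a 200 bp window (0.690%) and without replicate 1 (1.72%, against 4.14% without replicate 2), never past the threshold. Direction changed, without passing the threshold, for the E-box CAGCTG without GC matching (odds ratio 0.972), GAGA with 50 bp windows (0.704) and the homeobox motif on the 5 large chromosomes (0.989) and without replicate 2 (0.953, against 1.05 without replicate 1), though the homeobox motif passed without GC matching (1.37). Of the 54 named genes, 52 had a promoter summit, among them most of those named for a distal peak. Of these 52, 47 kept it in replicate 2's list and 49 in that of replicate 1. A further 28 classes, chromosomes, lists and motifs passed under no setting, and 33 of their 220 alternative values changed direction. For these changes the cause was not tested, except that fewer peaks or shorter windows enter some settings. Windows of 50 bp leave out the stretch 75 to 100 bp from the summit. In the even-ranked peaks the leading sequence had 29 matches there, against 10 within 25 bp. The replicate overlap and correlation need both replicates, so neither was left out there. No paired analysis was possible because there is a single group.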

Other observations

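Apart from the shares of ribosomal protein and tRNA genes, which were planned, the tests in this part were chosen after the data were examined, though the outcomes of the tests on 8-base sequences at ribosomal protein genes and on windows sharing 25 bases had not been seen when those tests were set. The highest signals lay in the parts of the chromosome arms next to the centromere. With windows bounded by eye (2L from 22 Mb, 2R up to 5.5 Mb, 3L from 23 Mb, 3R up to 4.5 Mb and X from 22 Mb), 57 of the 100 strongest peaks were centromere-proximal, 19 were on chromosome 4 and 24 on the rest of the arms. A promoter summit was present at 89 of 246 centromere-proximal genes (36.2%, 95% Wilson interval 30.4 to 42.4), against 1847 of 13619 genes on the rest of the arms (13.6%; odds ratio 3.62). As the windows were drawn around where these same peaks were strong, this describes the pattern and no p is given. The odds ratio was 5.24 with every window 1 Mb narrower and 1.71 with every window 1 Mb wider. Promoter summits there had a median signal of 602, and 488 on chromosome 4, against 93.6 on the rest of the arms. Summits outside promoters differed less, at 104, 118 and 83.2.

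Promoter summits lay on the upstream side of the TSS. Of the 1547 summits within 500 bp of a protein-coding TSS, 1284 (83.0%, 95% Wilson interval 81.0 to 84.8) were upstream. Over all 1547, downstream summits included, the median position was 77 bp upstream, with quartiles at 150 and 26 bp upstream. The leading sequence had a preferred strand at the same promoters. In the 200 bp each side of the TSS it was read as CCACTGTG on the gene's own strand at 53 of 68 promoter summits with a match (77.9%, 66.7 to 86.2; exact binomial test, p = 4.12e-06), with its median start 71 bp upstream.

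The first pattern weighed is the strength of promoter peaks next to centromeres and on chromosome 4, regions known for heterochromatin and repeats. Repeats collapsed in the assembly could raise signal throughout these regions. Conservative promoter summits there had a median signal 6.11 times that elsewhere (95% bootstrap interval 4.83 to 7.28). Ranked peaks outside promoters, taken at any IDR, had 0.868 times (0.852 to 0.883), with low medians of 15.4 there and 17.8 elsewhere. Conservative summits outside promoters were higher next to centromeres (median 104) and on chromosome 4 (118) than on the rest of the arms (83.2). A rise throughout as large as at promoters was seen in neither comparison, while a smaller rise stays open. Reads from transposable elements could place summits in them. Of the 151 promoter summits there, 2.65% (1.03 to 6.61) lay inside an annotated element, against 1.18% of all conservative summits. Such elements cover 16.7% of the sequence there, but their cover close to TSSs was not measured. As these summits were chosen for lying near a TSS, the low share does not decide whether reads came from elements. In replicate 1 the median signal of genes with a promoter summit was 325 next to centromeres, 247 on chromosome 4 and 59.7 on the rest of the arms. In replicate 2 it was 399, 344 and 61.3. The pattern thus did not rest on a single replicate, although the centromere-proximal windows were drawn around where these peaks were strong. The lowest odds ratio for a summit over both replicates and both regions was 4.74. Collapsed sequence at the promoters themselves was not measured and stays open, and no biological explanation was tested, as the design has a single group.

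The second pattern is the share of ribosomal protein genes, 64.8%. Heavily transcribed loci could be taken down without specific binding, and this stays open, since transcription was not measured here. Proteasome, oxidative phosphorylation and mitochondrial ribosomal protein genes together had a summit at 36 of 213 (odds ratio 1.29, 95% interval 0.899 to 1.84), which neither reaches nor excludes a rise of 1.5 times, and tRNA genes, at 3.10% (1.64 to 5.79) against 2.68% after shuffling (permutation test, p = 0.783), do not decide it either. If the peaks at ribosomal protein genes arose like other promoter peaks, they would hold the re-tested 8-base sequences as often. They held them at 34 of 57 summits (59.6%) against 1112 of 1602 (69.4%), an odds ratio of 0.647 (0.379 to 1.11), so the test does not decide.

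The third pattern is that the 8-base sequences lie to one side of the summit in one orientation. For 52 of the 56 sequences a strand and side were set in the odd-ranked peaks. On the set strand some sequences read CACTG and others CAGTG, as in TACACTGG and TACAGTGG. CACTG and CAGTG are thus not simply opposite strands of a single sequence here. Within 150 bp of the summit, 1134 even-ranked peaks held unequal numbers of matches on the set side and the opposite side, ties being left out. Of these, 789 (69.6%, 95% Wilson interval 66.8 to 72.2, exact binomial test, p = 1.52e-40) held more on the set side. Summits scattered at random around the sequence would give equal shares. Without windows that share 25 bases with another, 1110 of the 1134 remained and the share was 70.0%. The excess thus did not rest on such windows. Their removal could hardly lower the share, and copies without 25 identical bases were not sought, so copies of a repeat stay open. The share was 76.9% (73.4 to 80.1) outside promoters and 61.2% (57.0 to 65.2) at promoters, which argues against the direction of annotated genes as the whole cause. No biological explanation was tested.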
